A study of Mus musculus with 2 samples.

How the data were processed

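H3K4me2 ChIP-seq of mouse heart at embryonic day 11.5 was used as 1 group of 2 biological replicates, as the labels number them. Both carry the same donor identifier, which names the strain B6NCrl, and the labels state a fragment size of 300 to 500 bp. Per the file headers and manifests deposited with the samples, each list is in narrowPeak format on mm10: peaks were called for each replicate against a control, a pooled list was called on the alignments of both replicates together, and the replicated list was derived from these lists. The aligner, the peak caller, their versions, the control library and the rule behind the replicated list are not given in the sources used here. Per the deposited lists, each peak carries the authors' enrichment signal, a coverage-based value over the control whose exact scale is not stated, and the −log10 of the p-value and of the q-value from the authors' caller. The enrichment signal was used only to describe, rank or filter peaks within a list. The tests planned before the data were examined called this value fold enrichment; it is treated here as a signal of unstated scale, and no test depended on that. Peak lists contain no read counts, so depth is unknown and no interval on counting error was possible.

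Intervals listed several times with different summits were collapsed to 1 interval, and coordinates are printed 1-based on mm10. Genes, transcripts and tRNA genes were taken from GENCODE and RefSeq annotations of the same assembly, on which no interval ran past a chromosome end; intervals on unplaced scaffolds (11 in the replicated list) were left out of the work on genes. There were 21827 protein-coding genes with 41405 TSSs after 24 further gene identifiers that repeated a symbol were left out. Each such symbol was kept with its first identifier by position. A promoter was marked if an interval overlapped the 1 kb on either side of any of its TSSs. Breadth was the number of base pairs covered within 5 kb on either side of the TSS, taken at the TSS with the largest value and averaged over the replicates, so that it could not exceed 10 kb. Cover in this window need not lie at the gene's own promoter. Distal intervals lay more than 5 kb from every protein-coding TSS and were assigned to the nearest one. Broad domains were replicated intervals joined over at most 1 kb with a width of 5 kb or more, and distal clusters were distal intervals stitched over at most 12.5 kb.

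The gene lists were fixed before the data were examined, and some share members, such as Tbx3 of the cardiac transcription factors and the pacemaker genes; every member was found in the annotation except Ahsp of the erythroid list. Promoter marking and membership of broad domains were tested with two-sided Fisher's exact tests. Medians of breadth and of distal interval numbers were tested against 10000 random lists of the same size, for distal intervals matched on the length of the territory nearest to the gene, with a two-sided permutation p. Contrasts between lists used 100000 permutations, or every permutation where a list had under 10 genes. Benjamini-Hochberg adjustment ran over the lists, the 5 contrasts or the 18 motifs, and over the 3 contrasts with housekeeping genes among themselves. Chance overlap came from 100 shuffles of intervals within chromosomes, 20 for exon and intron classes. Motifs were searched as consensus strings on both strands within 250 bp of the summit of distal intervals and in windows 10 kb away that met no peak, with the reversed string as a control. The consensus strings were WGATAA for GATA, CTAWWWWTAG for MEF2, AGGTGT for T-box, TYAAGTG for NKX2, RCATTCC for TEAD, CATCTG for HAND, CAGCTG for the E-box, CCWWWWWWGG for CArG and ACCGGAAR for ETS. The remaining strings were ATTGTT for SOX, TGTTTAC for FOX, CAAAGTCCA for HNF4, GTTAATNATT for HNF1, TTCAGCACCNNGGACAG for REST, ATGCAAAT for OCT, CCASYAGRKGGC for CTCF, AGAGGAAGTG for PU.1 and TGASTCA for AP-1. GC matching drew windows from the same bins of 2%. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 with seed 11.

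Named genes followed a rule set before the data were examined: 9 genes of the heart, the 3 widest and 2 narrowest members of each list, genes in the 15 widest broad domains, and the nearest genes of the 10 largest distal clusters, of the 10 strongest replicated intervals and of the 5 strongest intervals of each replicate alone. Genes named beyond these as carriers of distal intervals or in the closing observations were chosen after their values were seen. On simulated lists of 20 genes, the list median test called 2% of 200 lists without effect and 98% of lists raised by 2 kb. The promoter test called 4.5% of lists without effect and 100% of fully marked lists, and the contrast test 5% without effect and 98.5% with a difference of 2 kb. These rates are for unadjusted p-values under 0.05. They do not carry over to adjusted calls, to shorter lists or to the matched tests of distal intervals. Covered base pairs matched a base-by-base count in all 1000 queries. Alternatives varied the overlap, the window, the distance, the list, the q-value threshold, the joining and stitching distances, the random lists and the flanks, and left out each replicate in turn. Matching on the number of TSSs, CpG matching for broad domains, the joint use of GC-matched flanks with a −log10 q of at least 5, and the contrasts with housekeeping genes were added after seeing the data.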

Results

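Dimethylation of lysine 4 on histone H3 (H3K4me2), a mark carried by promoters and by distal regulatory elements, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in hearts of mouse embryos at embryonic day 11.5. There was 1 group with 2 biological replicates from pooled male and female embryos of the strain B6NCrl. Replicate 1 held hearts of 109 embryos, and the number behind replicate 2 is not given in the sources used here. The deposited peak list of replicate 1 held 66790 distinct intervals covering 57.7 Mb, and that of replicate 2 held 69720 intervals covering 61.0 Mb (59.3 Mb ± 2.30, SD, n = 2). A list called on both replicates together held 55919 intervals, and the list of replicated peaks drawn from it held 50364 intervals with a median width of 721 bp. Read counts are not part of peak lists, so the sequencing depth behind each interval is unknown. With 1 tissue and 1 stage, the comparisons were replicate against replicate, gene list against gene list, and peak against surrounding sequence. The p-values below run across genes or peaks and not across replicates.

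The genes that direct heart formation were broadly covered by H3K4me2 in both replicates. Around the transcription start site (TSS) of Tbx5, a T-box factor of the atria and left ventricle, peaks covered the whole 10 kb window in both replicates (10000 bp ± 0, SD, n = 2). Cover reached 9942.5 bp ± 81.3 at Gata4, 9883 bp ± 165 at Hand2, 9761 bp ± 83.4 at Nkx2-5 and 9597 bp ± 202 at Tbx20 (SD, n = 2 throughout), all genes of transcription factors of the cardiac lineage. It was shorter at Myh6, the alpha myosin heavy chain (6274 bp ± 340), and at Mef2c, a muscle transcription factor (4784 bp ± 680), and shortest at Nppa, which encodes atrial natriuretic peptide (2292 bp ± 89.1). Tnnt2, cardiac troponin T, had the widest spread of these 9 genes (6946 bp ± 1566; 5839 bp in replicate 1 and 8053 bp in replicate 2). Genes near the limit of the 10 kb window, such as Tbx5 and Gata4, had little room to differ, and 16 of the 20 cardiac transcription factors were covered over more base pairs in replicate 2. So were 64.2% of the covered genes outside the erythroid list. The median of replicate 1 minus replicate 2 was -234 bp for the cardiac transcription factors. It was -161 bp in random lists matched on covered length (adjusted p = 0.89, permutation test). The interval over the TSS of Nkx2-5 ran from position 26835830 to 26846252 of chromosome 17 (mm10). That of Hand2 from 57316468 to 57337038 of chromosome 8 and that of Tnnt2 from 135836370 to 135841792 of chromosome 1. Over all 21827 protein-coding genes the covered length correlated between replicates with a Spearman coefficient of 0.986, and the median SD was 134 bp among the 15947 genes with any cover. This correlation runs across genes, which are not independent replicates.

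**Figure D1:**
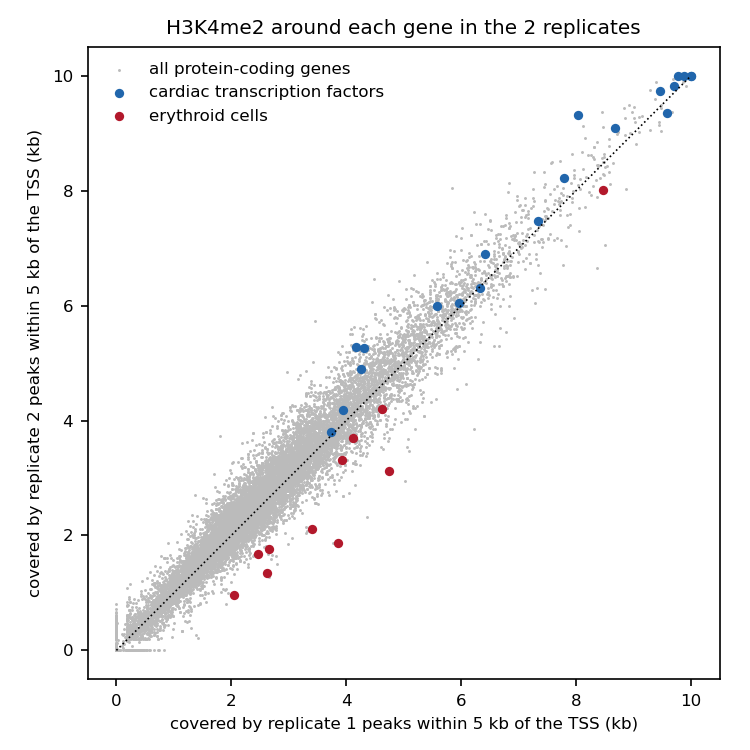
H3K4me2 cover of each protein-coding gene in the 2 replicates; the x axis gives the base pairs within 5 kb of the TSS covered by peaks of replicate 1 and the y axis those covered by peaks of replicate 2, both in kb, with 1 point per gene and a dotted line where both are equal. Of the 20 cardiac transcription factor genes (blue), 16 lie above the line, as do 64.2% of the covered genes outside the erythroid list. The 11 erythroid genes (red) lie below the line, with a median cover of 3851 bp in replicate 1 and 2117 bp in replicate 2.

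Of the replicate 1 peaks, 70.3% had at least 50% of their length inside replicate 2 peaks, against 2.41% ± 0.06 (SD over 100 shuffles) for shuffled positions, and 65.1% of replicate 2 peaks were shared with replicate 1 (2.25% ± 0.06 shuffled). Strong and wide peaks were shared most often. The share rose from 31.9% in the weakest 20% of replicate 1 peaks by the authors' enrichment value to 100% in the strongest 20%, and from 24.3% to 99.99% in replicate 2. Peaks present in both lists covered 49.7 Mb, which was 86.1% of the base pairs of replicate 1 and 81.5% of those of replicate 2. The enrichment ranks of matched peaks correlated with a Spearman coefficient of 0.815 over 50919 replicate 1 peaks. Intervals found in 1 replicate only, here meaning without any base in common with the other replicate's peaks, numbered 15871 in replicate 1 and 19357 in replicate 2. Their median widths were 218 bp and 231 bp, and 75.2% and 72.3% of them lay more than 5 kb from any protein-coding TSS. Among the 5 strongest intervals of replicate 1 alone were ones nearest to Spta1, the alpha spectrin of the red cell membrane, and Cpox, an enzyme of haem synthesis, together with intervals near Serp2, Capn13 and Tpt1. In replicate 2 alone the 5 strongest were nearest to Adgrg6, Ldlrad4, Cnnm3, Fgf18 and Egf. The replicated list was a subset of the pooled list and held 90.1% of it, and 92.5% of its intervals overlapped a peak of both replicates.

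H3K4me2 was concentrated at promoters. Of the replicated intervals, 34.3% overlapped the 1 kb on either side of a protein-coding TSS, against 3.32% ± 0.08 of shuffled intervals (SD over 100 shuffles), and they held 61.4% of the covered base pairs. The share was 27.3% ± 0.31 in the separate replicate lists (SD, n = 2). Introns held 32.5% of the replicated intervals (35.6% shuffled), intergenic sequence 29.3% (58.6% shuffled), coding exons outside promoters 2.79% (1.20% shuffled) and untranslated regions 1.20% (1.26% shuffled). The promoter class was assigned first and took 34.3% of real but 3.32% of shuffled intervals. A share of another class near or below its shuffled share therefore does not show depletion outside promoters. The 10 intervals with the highest enrichment value in the replicated list all covered a TSS. This is the authors' value, and its scale is not given in the sources used here. The 10 intervals were those of Nanos1, Ocln, which encodes the tight junction protein occludin, Rasgef1c, Srsf12, Rgs10, Znhit2, Frmd4b, Adamts17, Prss12 and Cdc14b. The promoters of 14838 genes were marked, which is 67.98% of the genes. The share followed the CpG content of the promoter, from 2.84% of genes in the lowest decile of the observed to expected CpG ratio to 99.5% in the highest. The X chromosome had 6.81 replicated intervals per Mb, the lowest density apart from the Y chromosome, and chromosome 11 the highest at 32.4.

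Every promoter was marked in the lists of cardiac transcription factors (20 of 20 genes, adjusted p = 0.0014), sarcomere and calcium handling genes (27 of 27, adjusted p = 0.00022), endocardial and endothelial genes (22 of 22, adjusted p = 0.0014) and BMP, Notch and neuregulin signalling genes (21 of 21, adjusted p = 0.0014), by Fisher's exact test against the other protein-coding genes. The same held for the 20 housekeeping genes (adjusted p = 0.0014), the 14 genes of cushion and valve mesenchyme (adjusted p = 0.014), the 12 genes of the second heart field and outflow tract (adjusted p = 0.022), and the 10 pacemaker and conduction genes and 10 smooth muscle and pericyte genes (adjusted p = 0.047 each, exact test). Genes of other tissues fell on both sides. None of 14 leukocyte promoters was marked (adjusted p = 9.1e-07, exact test). Among 20 hepatocyte promoters only that of Trf, which encodes transferrin, was marked (adjusted p = 6.3e-08, exact test). Marking was also less frequent in germ cells (3 of 14, Dmc1, Dazl and Ddx4, adjusted p = 0.0014), in gut, pancreas and lung epithelium (6 of 18, adjusted p = 0.0076), in skeletal muscle (9 of 21, adjusted p = 0.028, exact tests) and in olfactory receptors (5 of 1133). It was more frequent in neural transcription factors (18 of 20, adjusted p = 0.047), differentiated neurons (16 of 17, adjusted p = 0.028) and Hox genes (35 of 39, adjusted p = 0.0067, exact tests). The call of neural transcription factors was lost without replicate 1 (adjusted p = 0.061) or 2 (adjusted p = 0.065), and that of skeletal muscle without replicate 2 (11 of 21, adjusted p = 0.17) or with a window of 2.5 kb (adjusted p = 0.12, exact tests). Among intervals with a −log10 q of at least 5 the calls of pacemaker, smooth muscle, neural transcription factor and skeletal muscle genes (adjusted p = 0.053 each), cushion mesenchyme (13 of 14, adjusted p = 0.061) and Hox genes (32 of 39, adjusted p = 0.075, exact tests) were lost. Against lists matched on the number of TSSs, those of pacemaker, second heart field, smooth muscle, neuron and skeletal muscle genes were lost (adjusted p = 0.057 each, permutation test). Fisher's exact test did not pass for ventricular genes (7 of 7, adjusted p = 0.13), atrial genes (6 of 7, all but Sln, adjusted p = 0.46), epicardium (11 of 12, all but Msln, adjusted p = 0.14), neural crest and Schwann precursors (8 of 10, adjusted p = 0.52) and erythroid cells (10 of 11, adjusted p = 0.21). With 7 genes it could not have shown an excess. All 7 ventricular promoters were marked, and this highest possible share gave p = 0.11 (exact test).

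Against random genes with the same promoter CpG content, the sarcomere list stood out further, with 27 of 27 promoters marked where 48.7% was the mean of the random lists (adjusted p = 0.0011, permutation test). The 10 of 11 erythroid promoters compared with 18.7% (adjusted p = 0.0011), the 7 ventricular promoters with 60.51% (adjusted p = 0.0083, permutation test) and the 11 of 12 epicardial ones with 64.7% (adjusted p = 0.019). None of these 3 lists had passed against all other genes, though all 11 erythroid promoters were marked in each replicate alone (adjusted p = 0.036 without replicate 1 and without replicate 2, exact tests). Among intervals with a −log10 q of at least 5, only 5 of 11 erythroid promoters were marked, below the 67.1% of other genes (adjusted p = 0.21, exact test). Cardiac transcription factors (87.1% in random lists, adjusted p = 0.014), endothelium (81.7%, adjusted p = 0.014) and smooth muscle (58.8%, adjusted p = 0.012, permutation tests) kept their excess. The excess no longer passed for housekeeping genes, the second heart field, cushion mesenchyme, pacemaker genes, BMP and Notch signalling and differentiated neurons. Their random lists were themselves marked at 88.2% (neurons) to 98.2% (housekeeping genes), so little room was left for an excess. For neural transcription factors and Hox genes the share lay below that of the random lists without passing the test. The lower share no longer passed for skeletal muscle (adjusted p = 1) and gut, pancreas and lung epithelium (adjusted p = 0.076, permutation tests).

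Heart genes were covered over more DNA around the TSS than most genes. The median of the 20 cardiac transcription factors was 7705 bp ± 208 of the 10 kb window (SD of the replicate medians, n = 2), against 1928 bp over all genes. List medians given with an SD are the mean of the 2 replicate medians. The tests used the median of each gene's mean over the replicates, which differs in some lists, such as 2857 bp for the erythroid genes. The widest cover was at Gata6, Tbx5 and Gata4, the narrowest at Mef2a (3772 bp ± 46.7) and Hopx (4061 bp ± 165). Ventricular genes followed with 6315 bp ± 15.6, a list that shares 2 genes with the cardiac transcription factors and 3 with the sarcomere list. They were led by Prdm16 (8411 bp ± 40.3), Myh7, the beta myosin heavy chain (8352 bp ± 339), and Hey2, a Notch effector (7405 bp ± 103), and ended by Fhl2 and Myl3 (4714 bp ± 129). Sarcomere and calcium handling genes reached 5935 bp ± 25.5. They ran from Actc1, cardiac alpha actin (9484.5 bp ± 0.71), and Tpm1 (9136 bp ± 420) down to Ttn, which encodes titin (3542 bp ± 206), and Casq2, a calcium store protein (2781 bp ± 424). BMP, Notch and neuregulin signalling genes reached 5847.5 bp ± 237. Id2 (9223 bp ± 105), Smad7 (9131 bp ± 178) and Id3 (8429 bp ± 163), all targets of BMP signals, were widest there, and Heyl (1464 bp ± 34.6) and Bmp5 narrowest. For each of these 4 lists p was 0.0002, the smallest that 10000 random lists of the same size give (permutation test, adjusted p = 0.00051).

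Genes of the other cell types of the heart were also broadly covered. Cushion and valve mesenchyme had a median of 5647 bp ± 209. Sox9 (6916 bp ± 573), Prrx1 and Msx2 were widest, and Postn, an extracellular matrix protein of valves (1474 bp ± 140), and Tgfbr3 narrowest. Endocardium and endothelium had 4795 bp ± 61.2, from Tal1 (8385 bp ± 146), Nfatc1, a factor of valve endocardium (8047 bp ± 18.4), and Fli1 to Cldn5 and Emcn (2031 bp ± 31.1). The second heart field and outflow tract list had 4532.5 bp ± 393, with Wnt11 (8019 bp ± 643), Isl1 (6656 bp ± 351) and Tbx1 widest and Sema3c and Eya1 narrowest. Each of these 3 lists, and the housekeeping genes (4939 bp ± 21.2, from Tubb5 at 7598 bp ± 145, Gpi1 and Gapdh to Emc7 and Psmb2), had the same adjusted p of 0.00051 in the permutation test. Atrial genes had 4935 bp ± 144 (adjusted p = 0.0025, permutation test). Nr2f1 (9262 bp ± 307), Nr2f2, a determinant of atrial identity (8910 bp ± 79.9), and Myl4 were widest, with Kcna5 lower and Sln, which encodes sarcolipin, without any cover. Pacemaker and conduction genes had 4424 bp ± 165 (adjusted p = 0.0014, permutation test), led by Tbx3 (8005 bp ± 313), Hcn4, the pacemaker channel (6459 bp ± 298), and Cacna1h, with Hcn1 and Kcne1 lowest. Smooth muscle and pericyte genes had 3512 bp ± 343 (adjusted p = 0.025, permutation test), from Smtn (5161 bp ± 49.5), Cspg4 and Pdgfrb to Rgs5 and Myh11 (1274 bp ± 169). This last call was lost when the window was widened to 10 kb on either side (adjusted p = 0.099, permutation test). The epicardial list did not pass (2249 bp ± 297, adjusted p = 0.61, permutation test). Its 3 widest members were Wt1 (7249 bp ± 293), Tbx18 (5903 bp ± 528) and Tcf21 (4584 bp ± 253), while Upk1b had 1029 bp ± 330 and Msln, mesothelin, none.

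**Figure D2:**
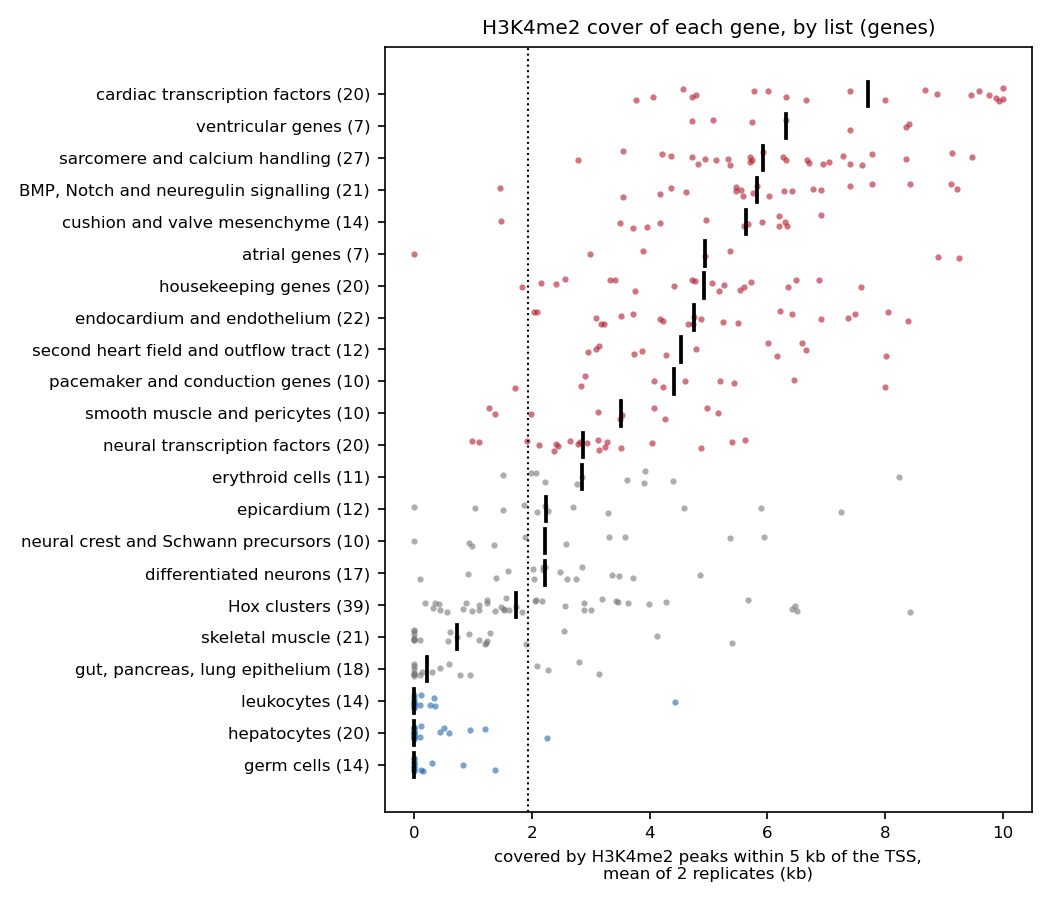
H3K4me2 cover of single genes by gene list; the x axis gives the base pairs within 5 kb of the TSS covered by peaks, as the mean of the 2 replicates in kb, each point is 1 gene, black bars mark list medians, the dotted line marks the median of all genes (1928 bp), and numbers of genes stand in brackets. Lists with an adjusted permutation p under 0.05 are drawn red where above random lists and blue where below, others grey; the olfactory receptors, with a median of 0 bp, are not drawn. The cardiac transcription factors lie highest, and the medians of leukocyte, hepatocyte and germ cell genes lie at 0.

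Among lists of other tissues, neural transcription factors lay above random lists (2868 bp ± 152, SD of replicate medians, n = 2, adjusted p = 0.045, permutation test), with Sox3 (5623 bp ± 554), Pou3f2 and Pax6 (4879 bp ± 469) widest and Neurog1 and Phox2b (978.5 bp ± 24.7) narrowest. That call was lost against lists matched on promoter CpG (adjusted p = 0.53) and with replicate 1 alone (adjusted p = 0.052, permutation tests). Differentiated neurons did not differ (2236 bp ± 59.4, adjusted p = 0.61, permutation test), and ran from Gad1 (4851 bp ± 229), Slc32a1 and Camk2a to Grin1 and Slc17a6. Nor did neural crest and Schwann precursors (2226 bp ± 68.9, adjusted p = 0.61, permutation test), from Tfap2a (5954 bp ± 443), Ednrb and Erbb3 to Sox10 (925 bp ± 286) and Plp1 with none. The Hox genes had a median of 1684.5 bp ± 46.0 (tested median 1739 bp, adjusted p = 0.61, permutation test). Hoxa2 (8435 bp ± 202), Hoxb2 (6500 bp ± 46.0) and Hoxa1 (6464 bp ± 249) lay far above Hoxc8 (329 bp ± 140) and Hoxc11 (177 bp ± 250). They lay below lists matched on promoter CpG, whose median was 2459 bp (adjusted p = 0.00046), and above random lists in a window of 10 kb on either side (3262 bp, adjusted p = 0.013, permutation tests). Skeletal muscle genes did not pass (726 bp ± 21.2, adjusted p = 0.12, permutation test). Mylpf (5396 bp ± 153), Casq1 and Actn3 were covered there, and Myh1 and Myh2, myosins of fast fibres, were not. Gut, pancreas and lung epithelium did not pass either (249.5 bp ± 89.1, adjusted p = 0.052, permutation test), led by Nkx2-1 (3140 bp ± 93.3), Foxa3 and Sftpc with Cpa1 and Fabp2 at 0. The promoter of Sftpc was not marked, and neither was that of Phox2b.

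The median gene was without any cover in hepatocytes (adjusted p = 0.025, permutation test), germ cells (adjusted p = 0.047), leukocytes (adjusted p = 0.049) and olfactory receptors (adjusted p = 0.00051). The most covered hepatocyte genes were the apolipoprotein genes Apoa2 (2262 bp ± 60.1, SD, n = 2) and Apoa1 (1212 bp ± 136) and the transferrin gene Trf, whereas Alb and Ahsg had none. The promoters of Apoa2 and Apoa1 themselves were not marked. In germ cells Dmc1 (1369 bp ± 80.6), Dazl and Ddx4 had cover and Mael and Piwil1 had none. Among leukocyte genes Cd68 had 4442 bp ± 203, C1qa had 353 bp ± 46.7, Cd79a had 338.5 bp ± 7.78, and Aif1 and Csf1r had none. No leukocyte promoter was marked, those of Cd68, C1qa and Cd79a included. The lower calls of leukocytes and germ cells were lost with either replicate alone (adjusted p = 0.061 and 0.057 without replicate 1, 0.055 and 0.052 without replicate 2, permutation tests), and those of leukocytes, hepatocytes and olfactory receptors against CpG-matched lists (adjusted p = 1 each). Over all genes, the median breadth was 0 in deciles 1 to 3 of promoter CpG. CpG matching thus left these lists little or no room to lie lower, and its loss of the calls decides nothing. Their promoter shares stayed lower against CpG-matched lists. The share was 0% of leukocyte promoters against 25.6% in the matched lists (adjusted p = 0.033, permutation test). It was 5% against 30.5% for hepatocytes (adjusted p = 0.016) and 0.44% against 12.0% for olfactory receptors (adjusted p = 0.00115, permutation tests).

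Erythroid genes were the list on which the replicates differed most. Their median cover was 3851 bp in replicate 1 and 2117 bp in replicate 2 (2984 bp ± 1226, SD, n = 2), and all 11 genes were covered over more base pairs in replicate 1. Nfe2, an erythroid transcription factor (8235 bp ± 323), Slc4a1, the anion exchanger of red cells (4407 bp ± 296), and Hemgn (3927 bp ± 1148) were widest, and the embryonic globin genes Hba-x (1983 bp ± 899) and Hbb-y (1504 bp ± 762) were narrowest. The list did not pass against random lists with the mean of both replicates (adjusted p = 0.15, permutation test) or without replicate 1 (adjusted p = 0.81), and it passed without replicate 2 (adjusted p = 0.0084), against CpG-matched lists (adjusted p = 0.00046) and in a window of 10 kb on either side (5785.5 bp, adjusted p = 0.00092). Among intervals with a −log10 q of at least 5 its median was 1729 bp, below the 1843 bp of random lists (adjusted p = 0.84, permutation test).

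Direct contrasts set heart lists against lists of other tissues, and ventricular against atrial genes, without matching on promoter CpG. Cardiac transcription factors were covered over 4376 bp more than neural transcription factors (7415 bp ± 2266 against 3039 bp ± 1224, SD over 20 genes each). Sarcomere and calcium handling genes exceeded skeletal muscle genes by 5029 bp (6123 bp ± 1617 over 27 genes against 1094 bp ± 1426 over 21), and endothelial genes exceeded hepatocyte genes by 4688 bp (4996 bp ± 1865 against 308 bp ± 581). In these 3 contrasts p was 1e-05, the smallest that 100000 permutations give, and the adjusted p was 1.7e-05. Epicardial genes exceeded gut, pancreas and lung epithelium by 2137 bp (2893 bp ± 2075 over 12 genes against 757 bp ± 1061 over 18, adjusted p = 0.00075, permutation test), but not in the number of distal peaks (adjusted p = 0.15). Ventricular and atrial genes could not be separated (6573 bp ± 1510 against 5049 bp ± 3262, 7 genes each, exact permutation p = 0.29), and by distal peaks the difference pointed the other way (3.29 against 7.29, adjusted p = 0.44, exact permutation test). Against housekeeping genes (4652 bp ± 1643), a contrast chosen after seeing the data, cardiac transcription factors were wider by 2763 bp (adjusted p = 0.00021, permutation test) and sarcomere genes by 1471 bp (adjusted p = 0.0054), and endothelial genes by 344 bp without passing the test (adjusted p = 0.53).

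Of the 15 widest H3K4me2 domains, 6 held genes of the cardiac transcription factor list, those of Gata4, Hand2, Nkx2-5, Tbx5, Tbx20 and Tbx2. After joining replicated intervals at most 1 kb apart, 1346 domains were 5 kb or wider, and 1433 genes had a TSS inside one. The widest was a domain of 27009 bp at Gata4 (chromosome 14, positions 63230148 to 63257156), which was covered to 91.6% by replicate 1 and to 98.4% by replicate 2. It was followed by 26393 bp at Hand2 (chromosome 8, 57311508 to 57337900), 25340 bp at Nr2f2, 23863 bp at Hoxa1, Hoxa2 and 5730596B20Rik, and 19056 bp at Bahcc1. Then came 18719 bp at Nkx2-5 (chromosome 17, 26835830 to 26854548), 18559 bp at Tbx5 (chromosome 5, 119827270 to 119845828), 18085 bp at Tbx20 and 17750 bp at Slc8a1, the sodium-calcium exchanger. Meis2 (17419 bp), Tbx2 (16537 bp), Arhgap23, Meis1 (16428 bp), Josd2 and Myh7 (16282 bp) completed the 15 widest. Of the cardiac transcription factors 17 of 20 had a TSS in a broad domain (adjusted p = 5.2e-17, Fisher's exact test), against 6.49% of other genes. So had 21 of 27 sarcomere genes (adjusted p = 2.9e-19), 15 of 21 of the BMP and Notch list (adjusted p = 3.6e-13) and 6 of 7 ventricular genes (adjusted p = 2.0e-06, exact tests). The ventricular share partly repeats those of the cardiac transcription factor and sarcomere lists, with which that list shares genes. Smaller shares that also passed were those of endothelium (11 of 22), cushion mesenchyme (8 of 14), second heart field (6 of 12), housekeeping (9 of 20), pacemaker (4 of 10) and atrial genes (3 of 7). The housekeeping share fell to 5% when intervals were not joined (adjusted p = 0.74) and when domains of at least 8 kb were counted (adjusted p = 0.38, exact tests). The pacemaker call was also lost at 8 kb (adjusted p = 0.23), and that of cushion mesenchyme without joining (adjusted p = 0.11, exact tests). Epicardial (3 of 12), smooth muscle (2 of 10), neural crest (2 of 10), erythroid (2 of 11), neural transcription factor (3 of 20) and Hox genes (5 of 39) did not pass. Among domains of at least 8 kb, epicardial (2 of 12, adjusted p = 0.025), neural crest (2 of 10, adjusted p = 0.021) and Hox genes (4 of 39, adjusted p = 0.0081, exact tests) did. Smooth muscle genes passed without replicate 1 (4 of 10, adjusted p = 0.012), Hox genes without replicate 2 (adjusted p = 0.033) and erythroid genes against CpG-matched lists (adjusted p = 0.030, exact and permutation tests). No gene of the neuron, skeletal muscle, hepatocyte, gut, leukocyte, germ cell and olfactory receptor lists lay in one.

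**Figure D3:**
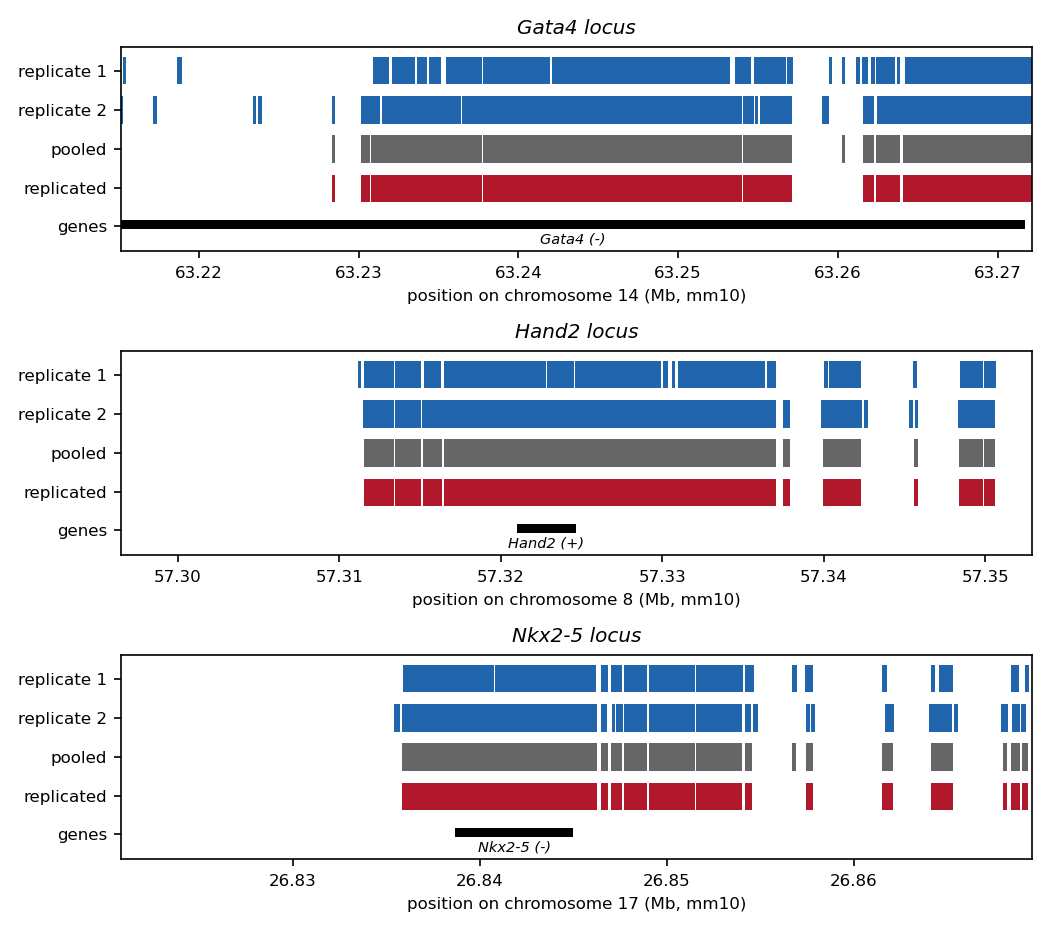
Maps of the H3K4me2 intervals at Gata4, Hand2 and Nkx2-5; the x axes give the position in Mb on mm10, bars are the deposited intervals of replicate 1, replicate 2, the pooled list and the replicated list, and black bars are protein-coding genes with their strand. Joined domains of 27009 bp at Gata4, 26393 bp at Hand2 and 18719 bp at Nkx2-5 are present in both replicates.

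Heart transcription factor genes had the most distal H3K4me2 intervals assigned to them. This count is not separate from the broad domains. At Nkx2-5, for example, the distal intervals from 26847033 to 26854548 of chromosome 17 lie inside its broad domain. A domain split into several intervals can add several to the count, and how far this raised the medians was not measured. The 20 cardiac transcription factors had a median of 10 replicated intervals more than 5 kb from any TSS, with 25 at Tbx3, 16 at Mef2c, 15 at Tbx5 and 11 at Hand2. Genes of BMP and Notch signalling had a median of 6, with 25 at Smad7. Random lists of genes with territories of similar length had a median of 1 in both cases (adjusted p = 0.0023 each, permutation test). Endothelial genes had a median of 3 (adjusted p = 0.0077), pacemaker genes 4.5, again with Tbx3 as the highest member, neural transcription factors 4 and sarcomere genes 2 (adjusted p = 0.021 each, permutation test). Cushion mesenchyme (median 5, 20 at Sox9, adjusted p = 0.068, permutation test), ventricular (3), atrial (3, with 29 at Nr2f2) and second heart field genes (3) did not pass, nor did the epicardial (1), neural crest (1.5), neuron (1) and gut lists (0.5). The smooth muscle, erythroid, leukocyte, skeletal muscle, hepatocyte, germ cell, housekeeping, Hox and olfactory receptor lists had a median of 0. At a distance of more than 2.5 kb cushion mesenchyme (adjusted p = 0.024) and ventricular genes (adjusted p = 0.041, permutation tests) passed. Without replicate 1 the medians were 16.5 for cardiac transcription factors, 6 for endothelial and 4 for sarcomere genes, and without replicate 2 they were 13, 5 and 4. The pacemaker call was lost among intervals with a −log10 q of at least 5 (median 2, adjusted p = 0.16, permutation test). When intervals had to lie more than 10 kb from a TSS, only the cardiac transcription factors passed (median 7, adjusted p = 0.0046, permutation test). The call of the neural transcription factors was lost without replicate 1 (adjusted p = 0.074, permutation test).

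Of the 26196 distal intervals, stitched into 16091 clusters, the clusters with most covered DNA lay near genes of several kinds. Clusters were ranked by the replicated list, and the separate replicates covered more DNA in the Cxxc5 cluster than in the first. The largest by that ranking covered 20143 bp within Igf2r, the imprinted receptor gene (chromosome 17, 12724077 to 12762209, with 20474 bp ± 1642 in the replicates, SD, n = 2). The next were in Cxxc5 (19122 bp, 26488 bp ± 1694 in the replicates; chromosome 18, 35814321 to 35895114), between genes with Il17b as the nearest (18745 bp, chromosome 18, 61632162 to 61676306), nearest to Cstad (18716 bp) and within Zfpm1, a GATA cofactor (18295 bp, chromosome 8, 122290043 to 122350189). Clusters nearest to Gpx5 (17847 bp), Btn1a1 (16528 bp) and Zfp184 (15954 bp) lay between genes on chromosome 13, and those at Rbpms (17615 bp, within the gene) and nearest to Scyl1 (16476 bp) completed the 10 largest. In all, 282 clusters held 5 kb or more of covered DNA, and 152 did when intervals were stitched over at most 5 kb.

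Recognition sequences of MEF2 and CTCF were the most enriched of 18 consensus motifs tested at distal intervals. The motif of MEF2, a family of muscle transcription factors, occurred within 250 bp of the summit in 3.33% of intervals and in 0.86% of flanks 10 kb away (log2 odds ratio 1.99 ± 0.11, SE; adjusted p = 3.8e-89, Fisher's exact test over 25560 windows). The motif of CTCF, an insulator protein, occurred in 2.71% against 0.32% (3.12 ± 0.17, adjusted p = 1.1e-122), though not within 100 bp of the summit (0.31, adjusted p = 0.57, Fisher's exact tests). ETS (1.167 ± 0.12), the E-box CAGCTG (0.95 ± 0.03), TEAD (0.69 ± 0.04), AP-1 (0.20 ± 0.04), GATA (0.16 ± 0.03) and FOX motifs (0.16 ± 0.05) were also more frequent at the intervals. SOX (-0.60 ± 0.03), T-box (-0.33 ± 0.03) and HAND motifs (-0.06 ± 0.03) were less frequent. The reversed HAND sequence was rarer still (-0.79 ± 0.04), so that HAND exceeded its control by 0.73 ± 0.05 (0.45 ± 0.05 with flanks matched on GC content), and reversed SOX was nearly as rare as SOX (-0.50 ± 0.03). HAND was itself less frequent at the intervals, so its difference from the control is no excess in peaks. The reversed HAND sequence matched 11.5% of peak windows against 34.1% for the motif, which makes it an unlike control. Peak windows were richer in GC than flanks (50.9% against 45.1%). With flanks matched on GC content the log2 odds ratio of GATA rose to 0.95 ± 0.03, where its reversed sequence gave 0.24 ± 0.03 (-0.59 ± 0.03 against unmatched flanks). The excess of GATA over its reversed sequence was thus 0.75 ± 0.04 unmatched and 0.70 ± 0.04 matched. With matched flanks the log2 odds ratio of MEF2 was 2.73 ± 0.14 (reversed 0.21 ± 0.20) and that of FOX 0.60 ± 0.06 (reversed 0.17 ± 0.05). NKX2 (0.27 ± 0.04, reversed 0.13 ± 0.05), OCT (0.51 ± 0.09, reversed 0.35 ± 0.30) and SOX (0.15 ± 0.04, reversed 0.23 ± 0.04) became more frequent in peaks, while T-box (-0.49 ± 0.03) and HAND (-0.17 ± 0.03) stayed less frequent. The E-box fell to 0.44 ± 0.03, above its reversed sequence (0.31 ± 0.14) by 0.13 ± 0.14, where the excess against unmatched flanks was 0.40 ± 0.13. The reversed E-box, GTCGAC, holds a CpG that CAGCTG lacks, and it matched 1.22% of peak windows against 33.8% for the motif. ETS holds a CpG that its reversed string lacks. The reversed strings of OCT and CTCF, and a form of that of TEAD, hold a CpG that their motifs lack. CpG content was not matched, so the reversed strings cannot show whether the excess of any of these motifs is specific to it. The GATA and FOX calls against unmatched flanks were lost among intervals with a −log10 q of at least 5 (adjusted p = 0.38 and 0.40, exact tests). PU.1, CArG, HNF4, HNF1 and REST, a repressor of neuronal genes whose motif matched 3 windows, did not pass with either kind of flank.

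**Figure D4:**
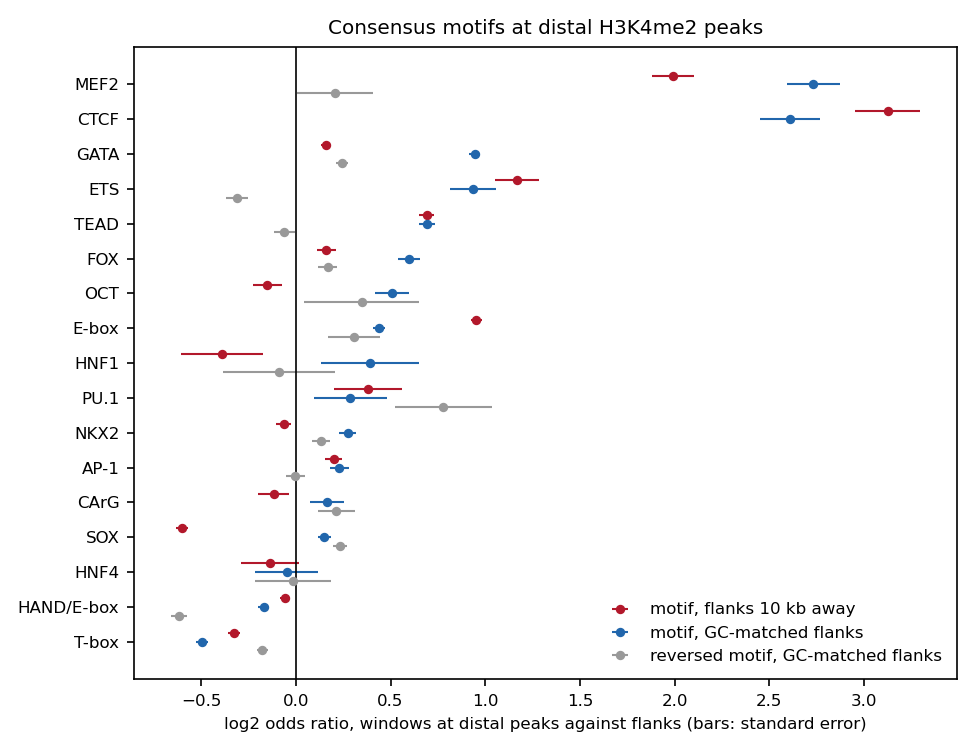
Log2 odds ratio of consensus motifs in windows at distal H3K4me2 intervals against flanking windows on the x axis, with standard errors as bars; red points use flanks 10 kb away, blue points flanks matched on GC content, and grey points the reversed motif against GC-matched flanks. Points with under 50 matching windows are left out, and so REST is not drawn. MEF2 and CTCF lie furthest to the right with both kinds of flank.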

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

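The contrasts with housekeeping genes, matching on the number of TSSs, CpG matching for broad domains and GC-matched flanks with a −log10 q of at least 5 were tests chosen only after the results were seen. Of 895 recomputed values, 771 stayed the same in direction, call or size, 60 lost a call, 24 gained one, 29 moved and 11 were counted as turned in direction. Among the 11 is a tie and not a true turn, the breadth of olfactory receptors with CpG matching, where both medians were 0. A turn was counted only where the value passed its test in at least 1 of the 2 settings, so that turns between values that passed in neither, such as erythroid genes with a −log10 q of at least 5, are among the 771. The causes of these changes between settings were not tested. No paired analysis was possible because there was 1 group. Depth is unknown, so what it limits could not be measured. The shares of peaks found in the other replicate (70.3% and 65.1%) became 76.2% and 72.2% with an overlap of 1 bp, 57.6% and 49.9% with 80% of the interval, 86.2% and 83.8% with a −log10 q of at least 5, and 94.1% and 95.8% among the strongest 20000. The rank correlation rose from 0.815 to 0.940 with reciprocal overlap and 0.879 with a −log10 q of at least 5. The promoter share of peaks (34.3%) was 32.6% with a window of 500 bp, 40.9% with 2.5 kb, 27.1% to 27.6% with a replicate left out, 31.4% in the pooled list, 45.5% with a −log10 q of at least 5 and 39.5% with all annotated genes. Lists with more frequent promoter marking numbered 12 as planned, 7 with a −log10 q of at least 5 and 7 with CpG matching. Of the last, 4 were among the 12, and ventricular, epicardial and erythroid genes were new. With CpG matching the shares of neural transcription factors (90%) and Hox clusters (89.7%) lay below the random lists. Lists with lower breadth numbered 2 in place of 4 with CpG matching, with replicate 1 or 2 left out (2 each), with a −log10 q of at least 5 and in the replicated list. With CpG matching the median of olfactory receptors (0) tied with that of random lists, also 0, so nothing could lie below it. With a 10 kb window the median of Hox clusters (3262 bp) lay above random lists. Lists with more distal peaks numbered 1 in place of 6 at a distance of 10 kb. The epicardial excess over gut, pancreas and lung epithelium, counted in distal peaks, was 1.06 (adjusted p = 0.15, permutation test). Broad domains numbered 565 without joining, 2502 from 4 kb and 268 from 8 kb (1346 at 5 kb), and distal clusters 152 with stitching over 5 kb (282 in the analysis as planned). With GC-matched flanks the log2 odds ratios of NKX2, SOX and OCT motifs turned to 0.27, 0.15 and 0.51, and to 0.27, 0.18 and 0.61 with a −log10 q of at least 5 as well; that of HAND was 0.029 within 100 bp of the summit.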

Other observations

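The tests on Hox genes, on promoters poor in CpG, on the width of calls at all genes, and on the distal clusters split by chromosome were chosen only after the result was seen, as were the tRNA counts. The test of the replicate difference in each gene list was not planned before the data were examined either. Transfer RNA genes, which are transcribed by RNA polymerase III, were marked by H3K4me2 in large number. Replicated intervals lay within 1 kb of 269 of 403 tRNA genes (66.7%; 67.1% ± 0.53 in the separate replicates, SD, n = 2), and of 100 of the 105 on chromosome 13. Of the 326 tRNA genes more than 5 kb from a protein-coding TSS, 199 (61.0%) were marked. No chance level is given for these tRNA shares, and the share of all tRNA genes was close to the 67.98% of protein-coding promoters. Over all 26196 distal intervals, 7.57% lay within 1 kb of the start of a non-coding or tRNA gene, against 1.99% ± 0.09 of shuffled intervals (SD over shuffles). That comparison rests mainly on non-coding genes, with 1840 intervals at their starts and 161 at tRNA gene starts.

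Several of the largest distal clusters held non-coding genes. Airn, a non-coding transcript of the imprinted Igf2r locus, started inside the largest cluster. The cluster nearest to Il17b on chromosome 18 held Bvht and Carmn, non-coding transcripts of the cardiovascular lineage, together with the microRNA genes Mir143 and Mir145a of smooth muscle. Malat1, a nuclear non-coding transcript, lay in the cluster nearest to Scyl1 on chromosome 19.

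Whether the 10 largest distal clusters mark gene starts that the protein-coding annotation leaves out was tested by the share of their intervals within 1 kb of a non-coding or tRNA gene start. Over the 10 clusters the share was 30.6% (49 of 160 intervals), against 7.42% of other distal intervals, which fell between the bounds set in advance. In the 3 clusters on chromosome 13, nearest to Gpx5, Btn1a1 and Zfp184 and holding 12, 10 and 14 tRNA genes, it was 85% (34 of 40). These clusters were split off after their tRNA genes had been seen, so this share describes them and does not support tRNA gene starts as the cause, which stays open. In the other 7 clusters, those at Igf2r, Cxxc5 and Zfpm1 among them, it was 13% (15 of 120), above the 7.42% of other distal intervals. This lay below a bound for gene starts as the source of most intervals, but that bound was written after the split. These 7 clusters are what the split left, so this share also only describes them. Most of their intervals lay away from the starts used here. No biological explanation of the rest was tested.

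Erythroid genes were covered over more base pairs in replicate 1 in 11 of 11 genes, with a median difference of 895 bp (p = 0.0002, the smallest that 10000 random lists give, adjusted p = 0.0044 over the lists, permutation test, the only list to pass). The difference at these 11 genes had been seen before it was tested on the same genes, so this p only describes it. Without passing, epicardial genes (-332 bp against -65.5 bp in random lists, adjusted p = 0.070) and smooth muscle genes (-404 bp against -104 bp, adjusted p = 0.15, permutation tests) leaned towards replicate 2. Wider calls in replicate 1 at all genes are argued against by the other 15936 genes with cover, where the median of replicate 1 minus replicate 2 was -87 bp, and wider calls at promoters poor in CpG by random lists matched on CpG and covered length, among which the erythroid list lay at percentile 100. More chromatin of red cell precursors in replicate 1 stays open: in another list of 30 erythroid genes written after the first list was seen but before its own test, and sharing no gene with any other list, 24 were wider in replicate 1 and 3 in replicate 2, and the median difference of 437.5 bp lay at percentile 100 of lists matched on covered length (p = 0.0002, again the smallest possible, permutation test). The largest differences were at globin genes, with 5026 bp in replicate 1 against 2945 bp in replicate 2 at Hba-a1 and 3851 bp against 1863 bp at Hbb-bh1. The labels name no sorting step that would remove blood, which makes a larger share of blood cells in the tissue of replicate 1 a candidate explanation, and the design gives no biological one between replicates.

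Among the 39 Hox genes, covered length fell with the paralogue number, with a Spearman coefficient across genes of -0.64 (permutation p = 8e-05, permuted within clusters). The 15 genes of paralogues 1 to 5 had a median of 3462.5 bp and the 24 genes of paralogues 6 to 13 one of 1362.5 bp; the median was lower in the posterior part of clusters a, b and c, and not in cluster d (1678.5 bp against 1533.5 bp). Promoter CpG content as the cause is argued against by the coefficient with CpG partialled out, which was -0.68 (permutation p = 8e-05). A dependence on the position along the cluster may therefore be kept as a hypothesis, found and tested on the same data; overlap of the windows of neighbouring genes was not tested.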
